A study of Escherichia coli with 12 samples.

How the data were processed

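The series compared wild-type Escherichia coli MG1655 from glycerol-limited aerobic chemostats before and after addition of an oxidant. Per the labels, the medium held 2 mM glycerol, the dilution rate was 0.2 per h, and oxygen was held at 40% of saturation with air. Once growth was steady, 300 µM of either oxidant was added to the vessel and to its feed. Samples of 10 ml were taken just before and 5 min after the addition. The labelling text of all 12 arrays speaks of hydrogen peroxide samples, while the titles and treatment texts name peroxynitrite for 6 of them. The groups follow the titles and treatment texts, and the labels do not settle the difference. Each agent was tested in 3 cultures, and 9 µg of RNA of each sample was labelled. Each culture gave 2 arrays on which the treated and the control RNA exchanged dyes, 12 arrays in all.

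The deposited file of each array gives foreground and local background intensity per spot for the Cy3 and the Cy5 channel, neither of them background-corrected per the file headers. The authors also deposited a log ratio of treated over control RNA for all but 281 of the spots, and 8 of those 281 name a gene. The base of the ratios is not stated. After plain background subtraction, recomputed log2 ratios had a slope of 0.999 to 1.12 on the authors' values over the 12 arrays, where values on a log10 scale would give 3.32, so the values were read as log2. The scanner, the image software and the authors' normalization are not given in the sources used here. The authors' log2 values correlated positively with the recomputed treated over control ratios on all 12 arrays (r = 0.908 to 0.987), and they were used as an alternative only.

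Spots were assigned to genes by the gene table of the probes, and symbols were updated to a current gene table for 197 spots. Of 4608 spots in 16 blocks, 4087 named a gene and 521 did not. The brightest spot was kept where a gene had more than 1, as 49 genes did, which left 4038 genes. Background was corrected with the normexp method of limma (offset 50), and log2 ratios were normalized within each array by loess, with spots that named no gene given a weight of 0. Ratios were turned to treated over control by the dye the labels give, and the 2 arrays of a culture were averaged, since they share their RNA. No gene was removed for low signal. A line without a spot address was dropped from 1 file. Analyses used R 4.3.3, limma 3.58.1 and statmod 1.5.0, and the figures were drawn with matplotlib 3.10.9.

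The 6 culture values of each gene were fitted with 1 mean per agent (lmFit and eBayes of limma), and both agents shared the estimate of the spread. Tested were each mean against 0 and their difference, peroxynitrite minus hydrogen peroxide, two-sided. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over the 4038 genes. The 2-fold threshold of the study was applied as a further filter. Errors are SD between the 3 cultures of an agent, and intervals are 95% confidence intervals of the fit. The 28 gene lists, with 495 different genes measured, were set from general knowledge of E. coli regulons and pathways. Each list was tested against all other genes with camera (preset inter-gene correlation of 0.01, adjusted over the 28 lists), and again with a correlation estimated from the data. Named genes were, for each agent, the 10 largest rises and 10 largest falls among genes that passed with the same sign in all 3 cultures. For the difference they were the 8 largest each way, and for each list the 3 members with the largest change, passing ones first. katG, ahpC, ahpF, oxyS, soxS, sodA, hmp, norV, cysK and recA were always included, and of these oxyS has no spot. The gene lists, this rule, the tests and most alternative settings were fixed before the data were examined.

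The pipeline was tested on simulated data with known changes. With peroxynitrite it recovered 16% of 1.5-fold rises, 84.5% of rises of log2 1 and all rises of log2 2. With hydrogen peroxide it recovered 24%, 84% and all of these, and it found 69.0% of true differences, which were of mixed sizes. Its estimates were too small: with peroxynitrite the median log2 was 0.458 for 1.5-fold, 0.852 for 1 and 1.72 for 2. On the real arrays the slope on the authors' values was 0.614 (peroxynitrite culture 3) to 1.04 (culture 1), so fold changes may be damped unequally. The simulated noise was independent between genes, with none added to the background, so real recovery may be lower. Each spot had the same simulated signal on all arrays, and each gene the same spread with both agents. Similar recovery with the 2 agents was therefore built in, and the weaker Cy5 signal of some hydrogen peroxide arrays was not reproduced. Among its peroxynitrite calls, 3.25% were false. No 2 arrays held identical values, and the highest r between arrays was 0.493. For arrays, precision is limited by their number. The p-values rest on 3 cultures per agent.

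Alternatives were: no background correction, plain background subtraction, median centring without loess, print-tip loess, scale normalization between arrays, removal of the 25% dimmest genes, all 12 arrays with culture as a random block, either dye orientation alone, each agent fitted alone, other eBayes and weighting options, the t test named in the study, the authors' values, the mean of a gene's spots, each culture left out, culture number as a block, a threshold of 0.01, and lists without shared genes. A dye term per gene and a filter on genes above background in both channels on at least 10 of the 12 arrays were added after seeing the data. Left out were spots that name no gene, which were fitted apart. No sample of a vehicle or of decomposed peroxynitrite is among the arrays, so the addition itself was not analysed here.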

Results

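Transcript levels in glycerol-limited chemostat cultures of Escherichia coli MG1655 were compared just before and 5 min after addition of 300 µM peroxynitrite, the oxidant formed from superoxide and nitric oxide, or of 300 µM hydrogen peroxide. There were 3 cultures per agent, each its own control, and 2 dye-swapped arrays per culture. Over the 12 arrays, the median spot intensity ranged from 227 to 742 in the Cy3 channel and from 134 to 647 in the Cy5 channel. Gene spots lying more than 2 SD above local background made up 61.1% to 99.6% in Cy3 and 28.5% to 97.6% in Cy5, and the lowest Cy5 shares, 28.5% and 31.1%, were on the arrays of hydrogen peroxide culture 1. Across genes, which are not independent replicates, the dye-swapped arrays of a culture correlated at r = 0.272 to 0.441 with peroxynitrite and at -0.231 to -0.0877 with hydrogen peroxide. Culture means correlated at 0.402 to 0.491 among the peroxynitrite cultures and at 0.0552 to 0.159 among the hydrogen peroxide cultures.

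The first comparison asked which transcripts changed within 5 min of peroxynitrite. katG, which encodes the catalase-peroxidase that removes hydrogen peroxide, rose 7.79-fold (log2 2.96 ± 0.17, SD, n = 3 cultures). The sulfate assimilation genes cysD and cysJ rose 7.74-fold (log2 2.95 ± 0.99) and 6.61-fold (2.72 ± 1.52), and ibpA, a small heat shock chaperone, rose 5.44-fold (2.44 ± 0.30). Of 14 genes for the assembly of iron-sulphur clusters, 13 rose. The glycerol channel gene glpF fell by 1.37 (SD 0.070) and the glycerol kinase gene glpK by 1.28 (SD 0.29) on the log2 scale. Of 4038 genes tested, 298 passed, 173 higher and 125 lower, and 120 of these changed at least 2-fold, 80 higher and 40 lower. The sign was the same in all 3 cultures for 293 of the 298, and 808 genes had an unadjusted p under 0.05.

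Among genes for oxidative damage and its repair, the OxyR regulon, the transcriptional response to peroxide, had 12 of 19 measured members that rose and 7 that did not pass, and 13 rose when adjusted over the list alone. Beside katG these included grxA, glutaredoxin 1 (log2 2.36 ± 0.81), ahpF and ahpC, the subunits of alkyl hydroperoxide reductase (1.82 ± 0.63 and 1.50 ± 0.67), and trxC, thioredoxin 2 (1.79 ± 0.67). The list's median log2 was 1.20 (camera, adjusted p = 4.45e-17), with adjusted p = 0.133 with an estimated correlation. The Isc and Suf list had 13 of 14 members that rose, and 14 when adjusted over the list alone, with a median of 1.29. It contained iscR, the cluster-sensing regulator of the isc genes (1.95 ± 0.36), iscS, the cysteine desulfurase (1.73 ± 0.23), and sufE, which passes sulphur to the Suf machinery (1.76 ± 0.58). It was the only list that passed with both correlations (adjusted p = 6.13e-20 with the preset, adjusted p = 0.0256 with an estimated correlation).

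The heat shock list rose in 10 of 18 members, and in 13 when adjusted over the list alone, with a median of 0.81 (adjusted p = 1.74e-12, and adjusted p = 0.121 with an estimated correlation). Examples beside ibpA were hslR, a heat shock protein that binds ribosomal subunits (log2 1.27 ± 0.44), and hslV, the peptidase of a heat shock protease (1.19 ± 0.37). Of 20 genes for thioredoxin, glutaredoxin, glutathione and repair of oxidised methionine, 4 rose, also over the list alone, with a median of 0.27 (adjusted p = 0.00875, and adjusted p = 0.364 with an estimated correlation). In the SoxRS regulon, the response to superoxide and redox cycling, 2 of 18 members rose, and 3 when adjusted over the list alone (median 0.24, adjusted p = 0.0107, and adjusted p = 0.373 with an estimated correlation). soxS, the regulator's own gene, rose 2.83-fold (1.50 ± 0.84), whereas sodA, manganese superoxide dismutase, had 0.14 ± 0.19 and did not pass. Without peroxynitrite culture 3, the thioredoxin and SoxRS lists no longer passed (adjusted p = 0.151 for each), nor did the thioredoxin list without genes shared with other lists (0.148). Leaving out culture 2 left 6 heat shock and 2 thioredoxin risers, leaving out culture 3 also left 2 thioredoxin risers, and the SoxRS list had 1 riser when any culture but peroxynitrite culture 1 was left out. fldA, which rose beside soxS, failed whichever culture was left out (adjusted p = 0.0542 to 0.238), also without culture 1 (0.0948). rimK of the SoxRS list came to pass there (0.0388).

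The nitric oxide list, targets of the NorR and NsrR regulators, rose in 1 of 14 members, and in 3 when adjusted over the list alone (median 0.21, adjusted p = 0.0307, and adjusted p = 0.267 with an estimated correlation). The riser was norR, the regulator of nitric oxide reductase (1.23 ± 0.53). hmp, the nitric oxide dioxygenase, had 0.23 ± 0.29 (adjusted p = 0.569) and norV, the reductase itself, 0.44 ± 0.42 (adjusted p = 0.197). Their spots were above background on 2 of 6 arrays in the treated channel. In the SOS list of DNA damage genes, 2 of 21 rose, and 3 over the list alone. yebG had 1.39 ± 0.98 and sulA, the inhibitor of cell division, 1.07 ± 0.67. recA, the SOS coprotease, had 0.41 ± 0.68 and did not pass. The SOS median was 0.23 (adjusted p = 0.00914, and adjusted p = 0.284 with an estimated correlation). Without peroxynitrite culture 2, yebG and sulA did not pass (adjusted p = 0.0942 and 0.159), nor did the nitric oxide list (0.0765), which also failed without culture 3 (0.075). No SOS gene passed without culture 2 (4 at an unadjusted p under 0.05), and 3 nitric oxide genes passed without culture 1.

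Some genes of sulfate assimilation were among the largest rises, and some of phosphate uptake rose as well. Of 30 measured targets of CysB, the activator of sulfate assimilation and cysteine synthesis, 20 rose and 10 did not pass. Adjusted over the list alone, 22 rose and 1 fell (median 1.50, adjusted p = 1.69e-19, and adjusted p = 0.1 with an estimated correlation). They covered sulfate import (cysP 2.40 ± 0.41, cysU 2.38 ± 0.93, cysW 2.41 ± 1.03) and the last step of cysteine synthesis (cysK 2.36 ± 0.60). Of 19 PhoB targets, which respond to low phosphate, 6 rose and 1 fell, and 7 rose and 2 fell over the list alone. The risers included pstS, the phosphate-binding protein (1.89 ± 0.73), pstB, the ATPase of the phosphate transporter (1.94 ± 0.37), and pstC, a membrane subunit of it (1.31 ± 0.65). The list's median was 0.0031 and its test did not pass (adjusted p = 0.113), but did upward without culture 2 (0.0454).

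Arginine synthesis genes rose in 8 of 13 members, and in 9 when adjusted over the list alone, with a median of 0.82 (adjusted p = 1.93e-06, and adjusted p = 0.336 with an estimated correlation). The cultures differed: the list's median was 1.27 and 1.98 in cultures 1 and 2 and -0.07 in culture 3. argI, ornithine carbamoyltransferase, had 2.67, 4.08 and -0.12 in the 3 cultures, and argA, which opens the pathway, had 1.85, 2.30 and 0.27. Without culture 2 neither passed (adjusted p = 0.239 and 0.107), and argI did not pass without culture 1 (0.0877). Of the 8 risers of the list, 0 remained without culture 2 (6 rose at an unadjusted p under 0.05) and 4 without culture 1 or hydrogen peroxide culture 1. Of 54 ribosomal protein genes, 11 rose, and 20 over the list alone, with a median of 0.39 (adjusted p = 8.4e-12, and adjusted p = 0.336 with an estimated correlation). The list's median was 0.71 and 0.46 in cultures 1 and 2 and 0.03 in culture 3, and rpmE, protein L31 of the large subunit, had 1.13 ± 0.43. Its 11 risers became 2 without culture 2. Of 13 genes of aromatic amino acid synthesis, 3 rose, and 4 over the list alone (median 0.37, adjusted p = 0.00582, and adjusted p = 0.192 with an estimated correlation). trpE, the entry enzyme of tryptophan synthesis, had 1.00 ± 0.57. Without culture 2 none of the 3 passed (adjusted p = 0.1 for trpE, 0.0952 for aroH and 0.127 for trpD), although 4 members did at an unadjusted p under 0.05.

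Smaller upward shifts were found for iron uptake, electrophile response, drug efflux and envelope stress genes. Of 34 Fur targets for iron uptake, 3 rose, and 3 rose and 1 fell over the list alone (median 0.27, adjusted p = 5.39e-04, and adjusted p = 0.373 with an estimated correlation). exbD and exbB, which energise uptake across the outer membrane, had 0.81 ± 0.34 and 0.79 ± 0.36. Of 13 genes of electrophile and reactive chlorine responses, 2 rose, also over the list alone (median 0.27, adjusted p = 0.00684, and adjusted p = 0.336 with an estimated correlation), among them yqhD, an aldehyde reductase (0.90 ± 0.56). Of 10 multidrug resistance genes, marA, the activator of drug efflux, rose (0.78 ± 0.53), also over the list alone (median 0.28, adjusted p = 0.0205, and adjusted p = 0.336 with an estimated correlation). Envelope stress genes passed as a list with none of 12 members passing alone (median 0.19, adjusted p = 0.0433, and adjusted p = 0.373 with an estimated correlation). The envelope list did not pass with median centring (adjusted p = 0.0755), print-tip loess (0.0826), Cy3 only (0.0806) or Cy5 only (0.247), or without the dimmest genes (0.0695). Without peroxynitrite culture 3, none of these 4 lists passed (adjusted p = 0.177, 0.151, 0.0594 and 0.065), nor did exbD, exbB, yqhD or marA (0.117, 0.119, 0.15 and 0.105). Without culture 2, the drug efflux and envelope lists did not pass (0.138 and 0.193), nor did marA (0.241) or yqhD (0.0621), and exbB did not without culture 1 (0.0624). The number of Fur targets that passed was 0 without culture 3 (3 rose and 1 fell at an unadjusted p under 0.05), and that of electrophile genes 0 without culture 2 or 3 (4 and 3 unadjusted).

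Some genes of glycerol use and of the citric acid cycle fell. Of 10 glycerol use genes, 4 fell, and 5 over the list alone, with a median of -0.48 (adjusted p = 1.74e-05, and adjusted p = 0.121 with an estimated correlation), and 2 fell without culture 2 or culture 3. Of 13 citric acid cycle genes, 4 fell, and 5 over the list alone (median -0.45, adjusted p = 4.47e-04, and adjusted p = 0.336 with an estimated correlation). Among them sucD of succinyl-CoA synthetase fell by 0.84 (SD 0.55) and did not pass without culture 2 (adjusted p = 0.236), nor did sucA and sucB of 2-oxoglutarate dehydrogenase (0.123 and 0.118), which also failed without culture 3 (0.238 and 0.191). The 4 falls became 0 without culture 2 (9 at an unadjusted p under 0.05), 1 without culture 3 or hydrogen peroxide culture 1 and 2 without culture 1. The cycle's median was -0.22 and -0.14 in cultures 1 and 2 and -1.01 in culture 3, and its adjusted p was 0.0369 without culture 3. None of 21 respiratory chain genes (median -0.21, adjusted p = 0.0107, and adjusted p = 0.452 with an estimated correlation) and none of 8 ATP synthase genes (median -0.23, adjusted p = 0.0433, and adjusted p = 0.491 with an estimated correlation) passed alone. Neither list passed without culture 3 (adjusted p = 0.438 and 0.73). Among the largest single falls, gatC, part of the galactitol transporter, fell by 1.50 (SD 0.19), lsrB, the binding protein for autoinducer-2, by 1.45 (SD 0.60). argT, the binding protein for lysine, arginine and ornithine, fell by 1.43 (SD 0.30), and cstA, a pyruvate transporter induced by carbon starvation, by 1.42 (SD 0.16).

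Of the 28 lists, 19 passed with peroxynitrite, 15 upward and 4 downward. Without culture 3, 9 of these no longer passed and 2 others came to pass, which left 12. With an estimated correlation 1 passed. The remaining lists did not pass. General stress genes (RpoS targets) had 1 of 18 members that rose and 1 that fell, and 1 and 2 over the list alone, with a median of -0.16 (adjusted p = 0.0541). Their median was -0.31 and -0.48 in cultures 1 and 2 and 0.24 in culture 3, and the list passed downward without culture 3 (adjusted p = 0.00115). Acid resistance genes had a median of -0.26 and none of 13 passing (adjusted p = 0.0528), and passed downward without culture 2 or 3 (0.0319 and 0.0334). Methionine synthesis had 1 of 15 that fell (median -0.08, adjusted p = 0.169), and histidine synthesis 1 of 8 that fell (median 0.02, mean -0.02, adjusted p = 0.872), counts that were the same over the list alone. The methionine gene metH did not pass without culture 2 or 3 or any hydrogen peroxide culture (adjusted p = 0.0507 to 0.376), and hisB did not without any 1 of the 6 cultures (0.0544 to 0.236). The riser of the general stress list did not pass without any 1 of the 3 peroxynitrite cultures. cbpA, which fell, did not pass without peroxynitrite culture 1 or 2 (adjusted p = 0.112 and 0.268) or hydrogen peroxide culture 1 or 2 (0.0529 and 0.0626). None passed, alone or over the list, among 17 branched-chain amino acid genes (median -0.06, adjusted p = 0.55) and 17 osmotic and ion transport genes (median -0.02, adjusted p = 0.883). The same held for 17 copper and zinc genes (median -0.02, adjusted p = 0.369) and 25 flagellar and chemotaxis genes (median -0.03, adjusted p = 0.564). The number of genes that passed fell to 113 without peroxynitrite culture 2, 183 without culture 3, 76 with plain background subtraction and 104 with the authors' values. Among genes above background on at least 10 of the 12 arrays, 290 passed, of which more were lower (156) than higher (134). The 2-fold count rose to 191 without culture 1, and the study's t test with its 2-fold threshold gave 63 genes, none after Benjamini-Hochberg adjustment (334 at an unadjusted p under 0.05 whatever the fold).

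**Figure D1:**
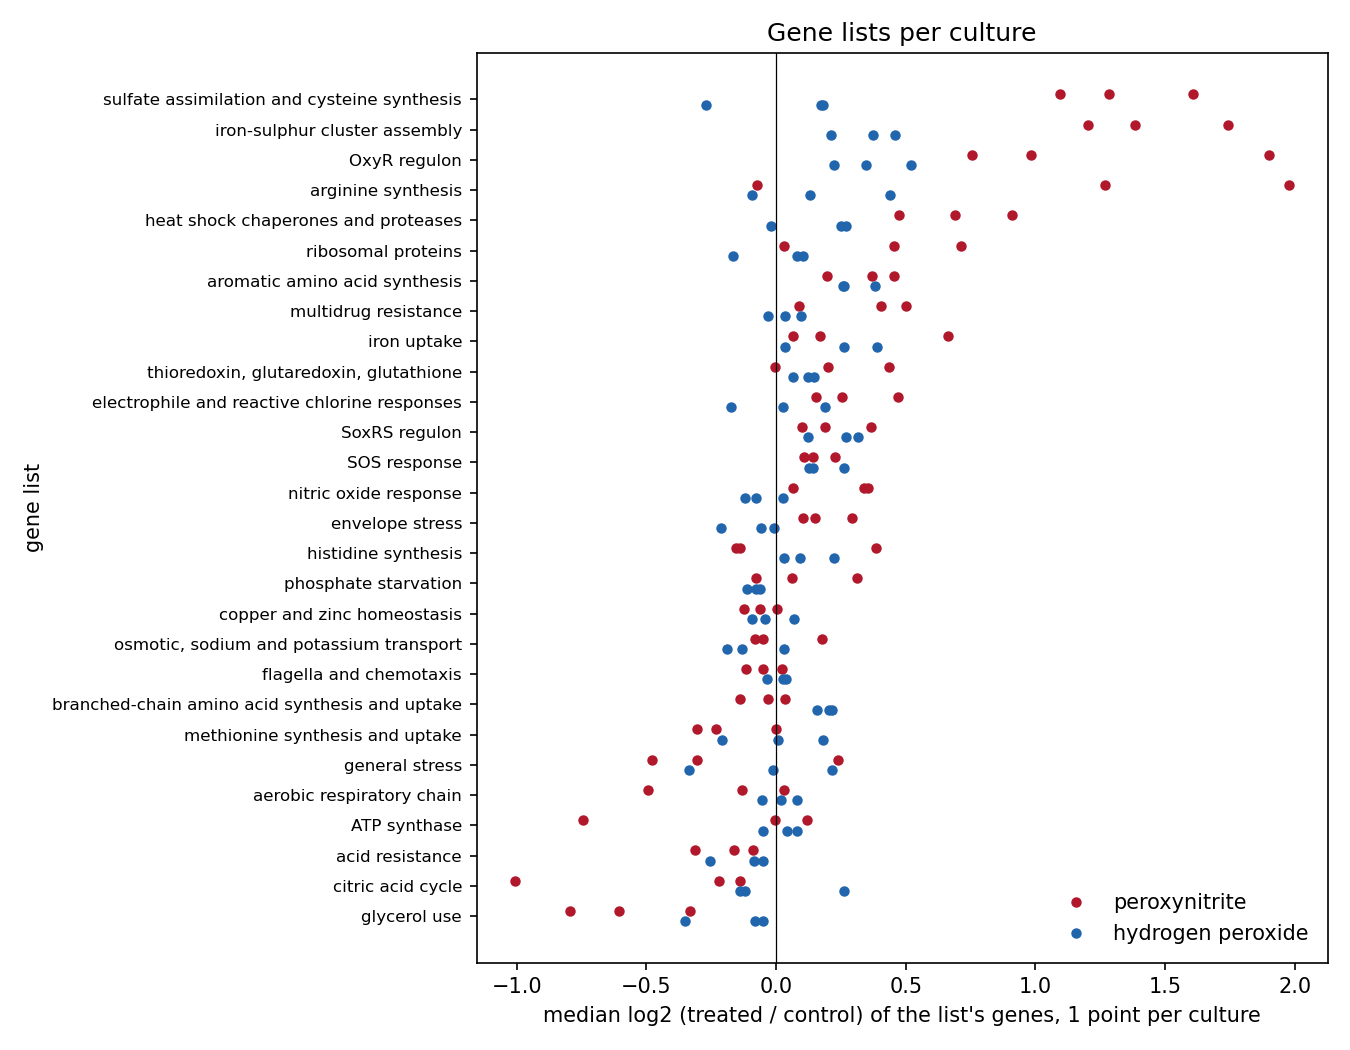
Median log2 of treated over control RNA of the genes of each list (x axis), 1 point per culture, for peroxynitrite (red) and hydrogen peroxide (blue), with lists on the y axis ordered by their median with peroxynitrite. The sulfate assimilation list has a median of 1.50 over the peroxynitrite means, and the arginine list lies at 1.27, 1.98 and -0.07 in the 3 peroxynitrite cultures.

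The next comparison asked which transcripts changed within 5 min of hydrogen peroxide. katG rose 7.66-fold (log2 2.94 ± 0.53, SD, n = 3 cultures), and the alkyl hydroperoxide reductase genes ahpC and ahpF rose 3.13-fold (1.65 ± 0.27) and 2.79-fold (1.48 ± 0.64). uxuB, uxaC and uxuA, enzymes that break down glucuronate and galacturonate, rose by log2 1.29 ± 0.24, 1.11 ± 0.19 and 0.95 ± 0.32. fumC, the oxidant-resistant fumarase of the SoxRS regulon, rose by 1.03 ± 0.39. These 7 genes were the only ones of 4038 that passed, 6 of them changed at least 2-fold, and 224 genes had an unadjusted p under 0.05. Without hydrogen peroxide culture 2, katG still passed, while the adjusted p was 0.153 for ahpC, 0.431 for ahpF, 0.267 for uxaC and 0.432 for each of uxuB, uxuA and fumC.

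By list, OxyR targets rose in 3 of 19 members, and in 7 when adjusted over the list alone, with a median of 0.29 (camera, adjusted p = 1.41e-12, and adjusted p = 0.257 with an estimated correlation). The 3 became 1 without hydrogen peroxide culture 1 or 2 and 5 without peroxynitrite culture 3. grxA had 1.43 ± 0.60 (adjusted p = 0.0561) and trxC 1.07 ± 0.48 (adjusted p = 0.136), and neither passed, although grxA did without peroxynitrite culture 2 or 3 (0.0121 and 0.0346), through the shared spread. SoxRS targets rose in 1 of 18, and in 3 over the list alone (median 0.30, adjusted p = 3.2e-07, and adjusted p = 0.261 with an estimated correlation). sodA had 0.79 ± 0.24 (adjusted p = 0.113), and soxS had a log2 of 0.0031 (SD 0.27, adjusted p = 0.997). Iron-sulphur cluster assembly genes had a median of 0.29 with none of 14 passing over all genes and 2 rising over the list alone (adjusted p = 1.81e-06, and adjusted p = 0.128 with an estimated correlation). Its member sufE had 0.94 ± 0.22. Fur targets for iron uptake likewise had none of 34 passing and 2 rising over the list alone (median 0.20, adjusted p = 1.81e-06, and adjusted p = 0.455 with an estimated correlation). entA of enterobactin synthesis had 1.08 ± 0.72 and passed without culture 3 (adjusted p = 0.0236).

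No member passed over all genes in the other lists that shifted. Aromatic amino acid synthesis had 3 of 13 rising over the list alone (median 0.26, adjusted p = 3.2e-07, and adjusted p = 0.128 with an estimated correlation), with aroF, an entry enzyme of the pathway, at 0.75 ± 0.062. Thioredoxin, glutaredoxin and glutathione genes had 2 of 20 rising over the list alone (median 0.07, adjusted p = 0.0194, and adjusted p = 0.585 with an estimated correlation), and did not pass without genes shared with other lists (0.557). The SOS list had a median of 0.21 and 1 of 21 falling over the list alone (adjusted p = 0.00235, and adjusted p = 0.261 with an estimated correlation). Upward shifts with no member passing even over the list alone were those of branched-chain amino acid genes (median 0.20, adjusted p = 0.00312, and adjusted p = 0.209 with an estimated correlation) and heat shock genes (median 0.20, adjusted p = 0.00539, and adjusted p = 0.455 with an estimated correlation). Of the 28 lists, 10 passed with hydrogen peroxide, 5 without culture 2 and 0 with an estimated correlation. Acid resistance genes shifted downward, again with none passing (median -0.08, adjusted p = 0.0352, and adjusted p = 0.375 with an estimated correlation). The acid resistance list did not pass without background correction (adjusted p = 0.0772), with print-tip loess (0.0619), with Cy3 only (0.477) or with Cy5 only (0.119). Without hydrogen peroxide culture 2, these lists did not pass for thioredoxin (adjusted p = 0.295), SOS (0.305), branched-chain amino acids (0.0821), heat shock (0.199) and acid resistance (0.0821). Heat shock and thioredoxin also failed without culture 3 (0.106 and 0.0805), and acid resistance without culture 1 (0.352). With the treated RNA in Cy5 only, the branched-chain and thioredoxin lists did not pass (adjusted p = 0.989 and 0.892). With Cy3 only the aromatic list did not (0.0538). Heat shock (0.14 with Cy3, 0.117 with Cy5) and SOS (0.253 and 0.0714) passed with neither orientation alone.

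CysB targets had no passing member with hydrogen peroxide, over all genes or over the list alone, and a median of 0.07 over 30 genes (adjusted p = 0.316), with cysK at -0.05 ± 0.50. The list passed upward without hydrogen peroxide culture 3 (adjusted p = 0.00617). No member passed either for arginine synthesis (median 0.15, adjusted p = 0.592), phosphate starvation (-0.02, adjusted p = 0.406) and nitric oxide response (-0.03, adjusted p = 0.798). Nor did any for ribosomal proteins (-0.0020, adjusted p = 0.679), glycerol use (-0.16, adjusted p = 0.145) and the citric acid cycle (0.04, adjusted p = 0.725). hmp and norV had -0.13 ± 0.37 and -0.13 ± 0.27, and recA 0.28 ± 0.31. Nor did the lists pass for general stress (adjusted p = 0.876, median -0.0044 and mean 0.03, with 1 gene rising over the list alone, and 0.0336 without culture 1), multidrug resistance (0.901, median 0.05 and mean -0.0012, with 1 falling over the list alone), methionine (0.876) and histidine (0.442). Nor did they for envelope stress (0.289), osmotic transport (0.443), copper and zinc (0.725), electrophile responses (0.888), the respiratory chain (0.876), ATP synthase (0.963, median -0.02 and mean 0.0098) and flagella (0.725). The 7 genes became 1 without hydrogen peroxide culture 1 or culture 2, 3 without culture 3 and 4 without peroxynitrite culture 1, through the shared spread. They became 1 with plain background subtraction or the authors' values. katG was the gene that remained in each of the 4 fits that left 1. Over the alternatives run for each gene, katG passed in 21 of 22, ahpC and uxaC in 15 of 22, uxuB in 9 of 21, ahpF in 8, fumC in 7 and uxuA in 6 of 22.

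**Figure D2:**
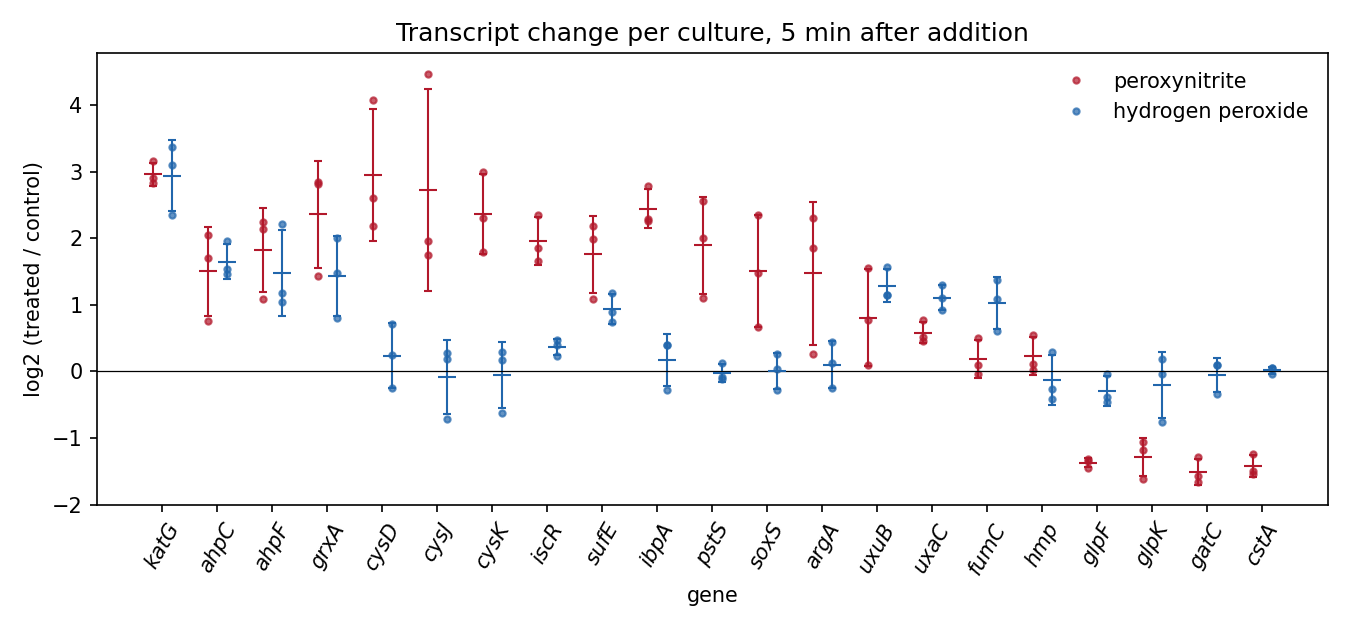
Log2 of treated over control RNA (y axis) of 21 genes (x axis), with 1 point per culture, the mean as a horizontal dash and bars of 1 SD, for peroxynitrite (red) and hydrogen peroxide (blue). katG has means of 2.96 and 2.94, while cysD has 2.95 with peroxynitrite and 0.24 with hydrogen peroxide.

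The last comparison asked where the responses to the agents differed at the same dose and time. Some of the sulfate assimilation genes were higher with peroxynitrite than with hydrogen peroxide. cysJ, the flavoprotein of sulfite reductase, differed by log2 2.81 (95% confidence interval 1.64 to 3.98, n = 3 cultures per agent). cysD differed by 2.71 (1.85 to 3.58), cysK by 2.42 (1.72 to 3.11) and cysC, adenylylsulfate kinase, by 2.34 (1.68 to 2.99). mcbA, a gene linked to biofilm mucoidy, differed by 2.88 (2.12 to 3.65) and the chaperone gene ibpA by 2.27 (1.70 to 2.84). Genes lower with peroxynitrite included pyrI, the regulatory chain of aspartate carbamoyltransferase (-1.51, -2.18 to -0.84), gatC (-1.45, -1.96 to -0.94) and cstA (-1.44, -1.92 to -0.96). In all 46 genes differed, 33 higher and 13 lower with peroxynitrite, each by at least 2-fold, and 494 had an unadjusted p under 0.05. Without hydrogen peroxide culture 3, the adjusted p was 0.146 for cysJ, 0.0707 for gatC and 0.179 for pyrI, while mcbA, cysD, cysK, cysC, ibpA and cstA passed whichever culture was left out.

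CysB targets differed in 13 of 30 members, and in 19 over the list alone, all higher with peroxynitrite (median difference 1.44, camera, adjusted p = 1.1e-17, and adjusted p = 0.116 with an estimated correlation). The 13 became 6 without hydrogen peroxide culture 3 and 7 without culture 1. Iron-sulphur cluster assembly differed in 4 of 14, and in 12 over the list alone (median 0.94, adjusted p = 7.99e-14, and adjusted p = 0.0542 with an estimated correlation). iscR differed by 1.59, sufS, the Suf cysteine desulfurase, by 1.60 and iscS by 1.16. Heat shock genes differed in 2 of 18, ibpA and hslR (1.21), and in 9 over the list alone (median 0.57, adjusted p = 1.24e-07, and adjusted p = 0.272 with an estimated correlation). Phosphate genes differed in 3 of 19, pstB (1.93), pstS (1.91) and phoU, the regulator of phosphate signalling (1.80). With hydrogen peroxide alone, phoU had -0.80 ± 0.87 (adjusted p = 0.535), pstB 0.01 and pstS -0.02, so part of the phoU difference is a fall that did not pass. Over the phosphate list alone 5 were higher and 1 lower with peroxynitrite (median 0.10, adjusted p = 0.036, and adjusted p = 0.338 with an estimated correlation). The phosphate list did not pass without peroxynitrite culture 3 (adjusted p = 0.118). Ribosomal protein genes differed in 1 of 54, rpmE (1.30), and in 11 over the list alone (median 0.43, adjusted p = 9.79e-11, and adjusted p = 0.431 with an estimated correlation). Arginine genes differed in none of 13, and in 4 over the list alone (median 0.78, adjusted p = 7.68e-05, and adjusted p = 0.459 with an estimated correlation). Without peroxynitrite culture 2 the arginine list did not pass (adjusted p = 0.0564). Leaving out peroxynitrite culture 3 gave 6 arginine and 5 ribosomal genes. The 4 iron-sulphur genes became 2 or 1 whichever culture was left out, the 2 heat shock genes 1 without peroxynitrite culture 2 or any 1 hydrogen peroxide culture, and the 3 phosphate genes 1 without hydrogen peroxide culture 1. iscR and pstB passed whichever culture was left out. Without hydrogen peroxide culture 3 the adjusted p was 0.12 for sufS, 0.149 for iscS, 0.119 for hslR, 0.0923 for phoU and 0.168 for rpmE, and without culture 1 it was 0.0751 for pstS.

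The peroxide-scavenging genes did not differ detectably: katG by 0.02 (-0.57 to 0.62), ahpC by -0.14 (-0.81 to 0.52) and ahpF by 0.34 (-0.42 to 1.10). OxyR targets as a list were higher with peroxynitrite in 1 of 19 members, sufS, and in 2 over the list alone (median 0.45, adjusted p = 6.51e-05, and adjusted p = 0.407 with an estimated correlation). The list did not differ when genes shared with other lists were left out (adjusted p = 0.156). The SoxRS list did not differ (median 0.08, mean -0.05, adjusted p = 0.557, with 1 gene higher over the list alone). soxS differed by 1.50 (0.75 to 2.25, adjusted p = 0.0595), fumC by -0.84 (-1.40 to -0.28, adjusted p = 0.18) and sodA by -0.65 (-1.16 to -0.14, adjusted p = 0.256), and none of these passed, although soxS did without peroxynitrite culture 1 (0.01). Nitric oxide genes were higher as a list with none of 14 passing and 1 over the list alone (median 0.28, adjusted p = 0.0324, and adjusted p = 0.276 with an estimated correlation). hmp differed by 0.35 (-0.21 to 0.92). recX, a regulator of the SOS protein RecA, differed by 1.21 (0.65 to 1.77) although it passed with neither agent, while the SOS list did not differ (adjusted p = 0.581). recX did not pass without hydrogen peroxide culture 3 (adjusted p = 0.23), nor did sufS (0.12).

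Lower with peroxynitrite were glycerol use genes, 1 of 10, glpF (-1.07), and 3 over the list alone (median -0.35, adjusted p = 0.00132, and adjusted p = 0.272 with an estimated correlation). glpF did not pass without any 1 of the 6 cultures (adjusted p = 0.058 to 0.219). Citric acid cycle genes were lower in none of 13 and in 4 over the list alone (median -0.54, adjusted p = 6.55e-04, and adjusted p = 0.407 with an estimated correlation). This list did not pass with the treated RNA in Cy3 only (adjusted p = 0.0713). With none passing alone or over the list, respiratory chain genes were lower as a list (median -0.21, adjusted p = 0.037, and adjusted p = 0.63 with an estimated correlation). So were branched-chain amino acid genes (median -0.17, adjusted p = 0.0324, and adjusted p = 0.276 with an estimated correlation). Envelope stress genes (median 0.30, adjusted p = 0.0177, and adjusted p = 0.407 with an estimated correlation) and electrophile response genes (median 0.29, adjusted p = 0.0124, and adjusted p = 0.407 with an estimated correlation) were higher in the same way. Each of these 4 lists, and the nitric oxide list, failed without each of at least 2 cultures. Without peroxynitrite culture 3 the adjusted p was 0.613 for the respiratory chain, 0.0743 for branched-chain amino acids, 0.166 for electrophile responses and 0.0743 for nitric oxide. For envelope stress it was 0.0809 without hydrogen peroxide culture 1. Lists that did not differ were those for methionine (adjusted p = 0.215, and 0.0143 lower without hydrogen peroxide culture 3), histidine (0.527, median 0.02 and mean -0.09, with 1 gene lower over the list alone), aromatic amino acids (0.724), iron uptake (0.706) and general stress (0.0674, and 0.00177 or 0.00285 lower without peroxynitrite culture 3 or hydrogen peroxide culture 1). Nor did those for acid resistance (0.706, median 0.15 and mean -0.04), osmotic transport (0.699), copper and zinc (0.299) and thioredoxin (0.215), or those for multidrug resistance (0.0675, with 2 higher over the list alone, and 0.0247 higher without peroxynitrite culture 1), ATP synthase (0.075, and 0.00638 lower without peroxynitrite culture 2) and flagella (0.449).

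Of the 298 genes that passed with peroxynitrite, 45 also differed from hydrogen peroxide and 253 did not. Both agents raised 5 genes, katG, ahpC, ahpF, uxuB and uxaC, where 0.300 would be shared between independent lists, and 1 remained without hydrogen peroxide culture 1 or 2, 2 without culture 3 and 3 without peroxynitrite culture 1. The mean responses correlated across genes at r = 0.193 (Spearman's rho = 0.129), and 0.359 or 0.380 with either dye orientation alone. With 1 orientation, a dye effect specific to each gene would stay in the ratios of both agents and raise this value. Single arrays of different agents had a mean r of 0.207 with the same orientation and -0.0972 with opposite ones. Among the 298 genes, 66.4% had the same sign with hydrogen peroxide, against 52.5% of the other genes. The number of differing genes fell to 13 without hydrogen peroxide culture 3, 14 without culture 1, 29 without culture 2 and 28 without peroxynitrite culture 2. It was 0 with plain background subtraction (315 at an unadjusted p under 0.05) or the authors' values (438).

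**Figure D3:**
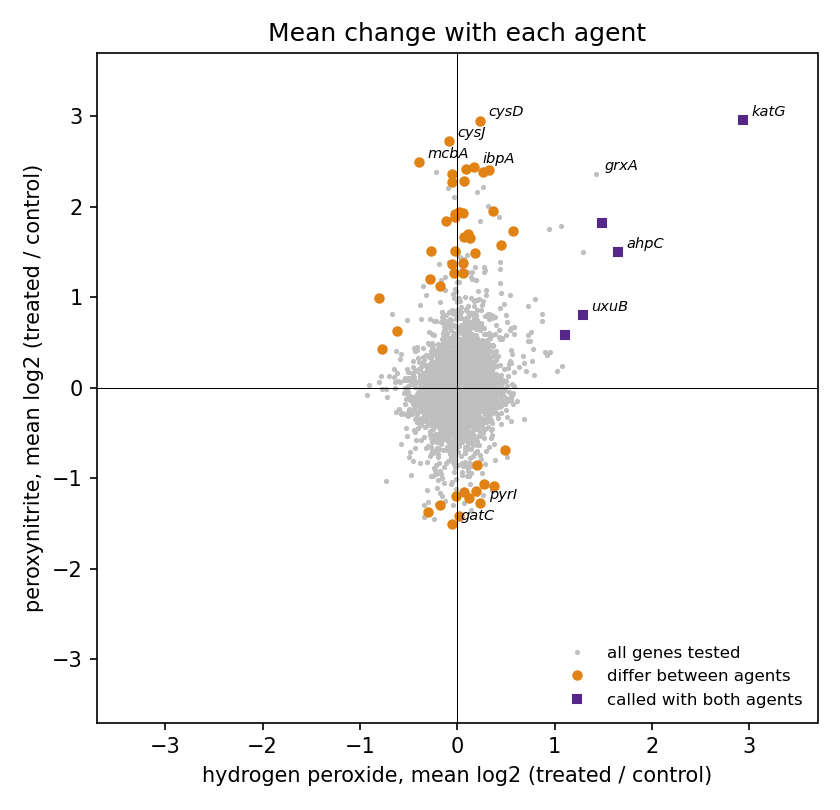
Mean log2 of treated over control RNA of each of 4038 genes with hydrogen peroxide (x axis) and with peroxynitrite (y axis). The 46 genes that differed between the agents (orange circles) lie mostly near 0 with hydrogen peroxide, and the 5 genes that passed with both (purple squares) include katG at 2.94 and 2.96.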

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

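The tests of the explanations weighed in this part were chosen after the results were seen, while the counts over other splits of the cultures were set beforehand.

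A difference between the agents was found for 46 genes, by a test of the difference itself (peroxynitrite minus hydrogen peroxide, n = 3 cultures per agent). Listed here are only the 26 of them that the rule for named genes picked. Higher with peroxynitrite, with their log2 differences, were mcbA (2.88), cysJ (2.81), cysD (2.71), cysK (2.42), cysC (2.34), cysW (2.32), ibpA (2.27), cysN (2.22), pstB (1.93), pstS (1.91), phoU (1.80), sufS (1.60), iscR (1.59), rpmE (1.30), hslR (1.21), recX (1.21) and iscS (1.16). Lower were glpF (-1.07), putP (-1.22), lldD (-1.33), gatZ (-1.33), gatB (-1.34), cstA (-1.44), gatC (-1.45), glaH (-1.46) and pyrI (-1.51). Among these 26 genes, mcbA, cysD, cysK, cysC, cysN, ibpA, pstB, iscR and cstA passed whichever culture was left out. The other 17 each failed without at least 1 culture, and those not given in the report reached an adjusted p of 0.149 (cysW), 0.203 (gatZ), 0.146 (gatB), 0.146 (lldD) and 0.134 (putP) without hydrogen peroxide culture 3, and 0.0907 (glaH) without culture 1.

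With the preset correlation, 14 gene lists differed as well. Their median log2 differences were 1.44 for sulfate assimilation, 0.94 for iron-sulphur cluster assembly, 0.78 for arginine synthesis, 0.57 for heat shock, 0.45 for OxyR targets and 0.43 for ribosomal proteins. They were 0.30 for envelope stress, 0.29 for electrophile responses, 0.28 for nitric oxide responses and 0.10 for phosphate starvation. Negative medians were those of the citric acid cycle (-0.54), glycerol use (-0.35), the respiratory chain (-0.21) and branched-chain amino acids (-0.17). With an estimated correlation, 0 of the 28 lists differed.

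The cultures were also divided in every other way. The numbers of splits given here include the real one, so 1 stands for the real split alone. Of the 4 splits of the signs of the 3 peroxynitrite cultures, 1 gave as many genes as the real one (298, highest other 0), 1 as many at 2-fold (120, highest other 0) and 1 as many lists (19, highest other 11). For hydrogen peroxide, 1 of 4 splits gave as many genes (7, highest other 0), 1 as many at 2-fold (6, highest other 0) and 2 as many lists (10, highest other 10). Of the 10 splits of the 6 cultures between the agents, 1 gave as many differing genes (46, highest other 0) and 1 as many lists (14, highest other 11). These splits are too few for a share under 0.05.

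Far fewer genes changed with hydrogen peroxide (7) than with peroxynitrite (298). A larger spread between the hydrogen peroxide cultures is argued against by the ratio of the median SDs, 0.854, with 42.7% of genes more variable with hydrogen peroxide. The fit shares the spread of each gene between the agents (median SE 0.179 for each), so this ratio does not itself test the counts. Weaker signal over background on the hydrogen peroxide arrays was not decided. Of 1391 genes above background on at least 10 of the 12 arrays, 2 changed with hydrogen peroxide and 290 with peroxynitrite. The 290 were 134 higher and 156 lower, with 212 of them among the 298. Such a gene can still lie below background on 2 hydrogen peroxide arrays, and 918 genes lay above it on all 6 in both channels. The filter also removes genes with a low control level. A single culture deciding the counts is argued against by the fits leaving out 1 culture, in which the lowest count with peroxynitrite was 113 and the highest with hydrogen peroxide 9. A difference in what the agents do to the cells stays open as a hypothesis, as does the addition itself, which was not analysed here.

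Dye-swapped arrays of each hydrogen peroxide culture correlated below 0 (r = -0.231 to -0.0877). A wrong dye orientation in the labels is argued against by katG, ahpC and ahpF, which all lay above 0 on 6 of 6 hydrogen peroxide arrays (katG 1.74 to 3.72, ahpC 0.99 to 2.10, ahpF 0.99 to 2.27). A dye effect specific to each gene remains a candidate explanation, since arrays of different agents correlated more with the same dye orientation than with the opposite one, by 0.305 in mean r. No biological explanation was tested.

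Arginine synthesis genes rose in peroxynitrite cultures 1 and 2 and not in culture 3, with 12, 12 and 4 of 13 members above 0. Log2 ratios damped by weak signal on the arrays of culture 3 are argued against by the 6 members above background in both channels on both of its arrays. Their median was -0.074 in culture 3, against 1.17 and 2.35 in cultures 1 and 2, and the share of the list's spots above background was 100% in culture 1, 53.8% in culture 2 and 57.7% in culture 3. A fault of 1 of the 2 arrays of culture 3 is argued against by the list's medians on them, -0.038 and -0.20, against 1.11 to 2.43 on the 4 arrays of cultures 1 and 2. The design has no group that separates culture 3, so no biological explanation was tested.

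Among 248 spots that name no gene, signals outside the gene comparisons were found for 8 spots with peroxynitrite, 5 higher and 3 lower (largest log2 1.23), and for 1 spot in the difference (1.45). An array far from the others was the first array of hydrogen peroxide culture 1, with a median Cy5 background intensity of 64.5, the lowest of 6. It was the 1 case in 16 groups of arrays tested, and chance gives about 1 in 20.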

How the results depend on the processing

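The fits with a dye term per gene and with genes above background on at least 10 of the 12 arrays were chosen after the results were seen.

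Over the at most 22 settings run for the named genes, 5697 of 6351 values kept their side of the threshold, 584 no longer passed and 70 came to pass. Values that passed neither before nor after count as kept, so these numbers do not measure how stable the calls were. Of the lost values, 309 were with peroxynitrite, 203 in the difference and 72 with hydrogen peroxide, where only 7 of 92 named genes had passed. The sign changed for 74 values, 0 of which passed before or after. The mean of a gene's spots, the threshold of 0.01 and the fits chosen later were run for the counts of genes only. For the gene lists, under their own settings, the numbers were 1191, 124 and 29 of 1344, and 62 changed sign, again 0 of them passing before or after. Lists that passed neither before nor after are likewise among the 1191. Over the settings of background and normalization, the median log2 of all genes lay between -0.0198 and 0.0023 with peroxynitrite and between -0.0041 and 0.0082 with hydrogen peroxide. Loess and median centring bring the ratios of each array near 0, so these medians do not test the processing. The mean correlation of dye-swapped arrays (0.0882) became -0.0277 with median centring, a move beyond the SD between cultures of an agent (0.0837), and lay between 0.0286 and 0.160 under the other settings.

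The 298 genes changed by peroxynitrite became 76 with plain background subtraction, which tested 2831 genes, 115 with the treated RNA in Cy5 only, 145 with each agent fitted alone, 104 with the authors' values (103 of them among the 298) and 111 at an adjusted p under 0.01. Leaving out 1 culture gave 113 to 341. The 120 genes at 2-fold became 73 with plain background subtraction and 186 with the treated RNA in Cy3 only, and 90 to 191 without 1 culture. The study's t test at 2-fold, unadjusted, gave 63 genes. After Benjamini-Hochberg adjustment it gave 0, with 334 genes at an unadjusted p under 0.05.

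The 7 genes changed by hydrogen peroxide became 1 with plain background subtraction or the authors' values, 3 with median centring without loess, 3 without the dimmest genes, 3 with the treated RNA in Cy3 only, 4 with print-tip loess, 4 with Cy5 only and 2 at an adjusted p under 0.01 or among genes above background. They became 14 with culture as a random block, 13 with a dye term per gene and 17 with arrayWeights, and 1 to 9 without 1 culture. The correlation estimated within cultures was -0.0898 with the random block and 0.113 with the dye term. These 2 fits therefore counted the 2 arrays of a culture nearly as separate replicates, here and in their counts below. The t test gave 0 after adjustment, with 226 unadjusted. At 2-fold, 6 became 1 with plain background subtraction or the authors' values, 3 with median centring, without the dimmest genes or with Cy3 only, 11 with arrayWeights, 2 at 0.01 or above background and 0 with the adjusted t test, and 1 to 8 without 1 culture.

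The 46 differing genes became 0 with plain background subtraction (315 unadjusted) or the authors' values (438 unadjusted), 29 with median centring, 15 with Cy3 only, 3 with Cy5 only and 15 at 0.01. They became 97 with culture as a random block and 95 with a dye term per gene, fits that counted the 2 arrays of a culture nearly as separate replicates. Without 1 culture they became 13 to 62. The t test gave 76 at 2-fold, unadjusted, and 0 after adjustment (346 unadjusted). The fit was set beforehand without pairing of cultures. After each agent's mean was taken off, cultures of the same number in the 2 agents correlated at r = 0.0956, -0.0334 and 0.0967. Those of different numbers correlated at -0.132 to 0.0466. With culture number as a replicate block, 74 genes differed, 55 higher and 19 lower, and these held all 46.

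The 5 genes changed by both agents became 1 with plain background subtraction, the authors' values or the unadjusted t test, 2 with median centring, at 0.01 or above background, 3 without the dimmest genes or with Cy3 only, 9 with culture as a random block or a dye term per gene and 0 with the adjusted t test, and 1 to 5 without 1 culture. The correlation of the responses, 0.193, became 0.359 with Cy3 only and 0.380 with Cy5 only, where a dye effect specific to each gene would not average out. The 19 gene lists shifted by peroxynitrite became 10 with Cy3 only and 1 with an estimated correlation, and 12 to 19 without 1 culture. For hydrogen peroxide 10 lists became 6 with Cy5 only and 0 with an estimated correlation, and 5 to 10 without 1 culture. The 14 differing lists became 0 with an estimated correlation, and numbered 10 to 14 without 1 culture. For all changes in this part, the cause was not tested.

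Signal over background limits the dimmer genes most in Cy5, where 28.5% to 97.6% of spots lay above it. The files hold no spot flags and no scan date or slide batch, so settings based on these were not run. The difference between agents was not run with each agent fitted alone.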

Other observations

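The gene groups in this part were chosen after their values were seen, as was the test of OxyR targets, and the groups were not recomputed under other settings.

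With peroxynitrite, all 6 galactitol genes (gat) fell, with a median log2 of -1.10 (-1.50 to -0.85), against 0.12 with hydrogen peroxide, and 4 of them differed between the agents, 1 without culture 1 of either agent and 0 without hydrogen peroxide culture 3 (6 at an unadjusted p under 0.05). Of 8 autoinducer-2 genes (lsr), 5 fell (median -0.71), as did 6 of 9 acetate and lactate genes (-0.94), 5 of 11 maltose genes (-0.29), 3 of 12 purine synthesis genes (-0.49), 3 of 4 fumarate reductase genes (-0.77) and 3 of 7 fatty acid breakdown genes (-0.68). With hydrogen peroxide the medians of these 6 groups were -0.26, -0.03, -0.15, 0.12, -0.38 and -0.09, none of their genes passed, and only 1 acetate and lactate gene differed between the agents. Without peroxynitrite culture 2 the falling genes of the 6 groups numbered 2, 4, 3, 2, 0 (4 at an unadjusted p under 0.05) and 1, and without culture 3 they numbered 3, 6, 4, 1, 1 and 2. purM of purine synthesis had -1.35, and -0.52 without culture 3 (adjusted p = 0.173). All 5 genes of the phosphate transporter operon rose (median 1.31, -0.02 with hydrogen peroxide). Both thiosulfate uptake genes rose with peroxynitrite (median 1.77), as did 4 of 5 genes of the operon of iaaA and the glutathione importer (0.94; iaaA and gsiA, gsiB and gsiC) and 3 of 7 phage shock genes (0.50). Their medians with hydrogen peroxide were 0.07, -0.0033 and -0.11. Without culture 2, and also without culture 3, both thiosulfate genes rose, 1 gene of the importer operon and 0 phage shock genes (4 and 3 at an unadjusted p under 0.05). Of 8 hexuronate genes, 2 rose with peroxynitrite (median 0.40) and 3 with hydrogen peroxide (0.70). The 2 became 0 when any culture but peroxynitrite culture 1 was left out (2 to 5 at an unadjusted p under 0.05), and the 3 became 0 without any 1 of the hydrogen peroxide cultures (6, 4 and 5 at an unadjusted p under 0.05).

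Of 298 genes changed by peroxynitrite, 194 were in none of the 28 lists. Among genes that varied between the cultures, ybiJ had log2 values of 0.62, 1.91 and 4.63 with peroxynitrite, and azoR 0.64, 2.06 and 3.62. The spots of deaD differed from each other by more than 1 on the log2 scale.

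OxyR targets outside the suf operon had a mean log2 above 0 with both agents, although with hydrogen peroxide 3 of them passed (katG, ahpC and ahpF) and dsbG (-0.18) and mntH (-0.09) lay below 0. A candidate explanation is hydrogen peroxide present in the peroxynitrite solution. Over 13 such genes the mean log2 was 1.13 with peroxynitrite and 0.84 with hydrogen peroxide, a difference of 0.30 (SE 0.25, exact permutation p = 0.5, smallest possible 0.1, n = 3 cultures per agent). Of the 13 genes, 11 were higher with peroxynitrite and 0 differed (adjusted p under 0.05 in limma). The values decide neither for nor against this explanation, since the arrays hold no control solution.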
